A study of Mus musculus with 4 samples.

How the data were processed

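RNA of 4 cultures of mouse EML cells, 2 KIT mutants each without and with SCF, was hybridised to Affymetrix mouse oligonucleotide arrays, 1 array per culture, and scanned and quantified with Affymetrix software, per the labels' protocols and the series' design text. The deposited values were made with RMA, per the submitters' processing notes; the RMA version is not given in the sources used here. The authors' table is taken as log2 because RMA gives log2 values, although no source states the base; the largest difference between arrays was 8.65. Probe set values lie around 0, with 87.9% to 94.1% of the 10861 values of an array within 1 of it, so each probe set had been set relative to some level. That level was not the mean of these 4 arrays: only 56 probe sets had a mean within 0.002 of 0. What it was is not given in the sources used here. Array medians were -0.02, -0.10, -0.05 and -0.20 for Del417-419insY and D816V without SCF and Del417-419insY and D816V with SCF. The table used here holds 10861 of the 45101 probe sets that the design text states for the array, by a filter that the sources used here do not give, so counts refer to these probe sets. A filter that kept variable probe sets would raise shares of differing genes. Signal over background could not be examined, since no brightness or detection value was used here, and no background correction or slide effect could be tried from processed values.

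Gene symbols came from the platform annotation, in which 9633 probe sets had 1 symbol, 264 several and 964 none. Symbols were checked through the gene ID against the RefSeq annotation of assembly GRCm38.p6; 11 probe sets had an ID without a match and kept their symbol. Probe sets with several symbols or none were left out of the gene counts. The value of a gene was the mean of its probe sets, which gave 6404 genes, 4203 with 1 probe set and 2201 with more. No coordinates were used.

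The planned analysis had assumed absolute brightness. Because the table holds relative values, 3 points changed after the values were seen: no filter on dim probe sets was applied, the mean of a gene's probe sets took the place of the probe set with the highest mean, and random lists were matched on the number of probe sets per gene (1, 2, or 3 and more) in place of mean expression. Both planned choices that could still be computed were kept as alternatives. The comparisons, the limma fit, the members of the 22 gene lists and, apart from these 3 points, the rule for named genes were fixed before the data were examined. Chosen after the values were seen were 2 alternatives named below, 4 further gene groups, the tests against ligand responses and a requirement on random lists in the test of amino acid stress genes.

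Differences are D816V minus Del417-419insY and SCF minus no SCF, on the log2 scale. With 1 array per group no single difference could be tested. Genes were counted where a difference was 2-fold or more, and where both differences from separate arrays were 2-fold or more in 1 direction. The number that independent lists would share is the product of the list sizes over the number of genes. The only test was limma 3.58.1 in R 4.3.3, lmFit and eBayes on ~ genotype + SCF over all 4 arrays, with Benjamini-Hochberg adjusted p under 0.05 over 6404 genes, two-sided. This fit leaves 1 residual degree of freedom per gene, the difference between the SCF responses, and takes it for error; the prior had 4.1 degrees of freedom and an SD of 0.127. Each mutant was 1 transduced population and nothing in the labels names repeat cultures, so p-values cover neither repeat arrays nor repeat populations. They set the mean difference of a gene against the difference between its SCF responses, moderated by the prior. A difference between the SCF responses could not be tested.

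The 22 gene lists covered mast cell, erythroid, megakaryocyte, granulocyte and monocyte, lymphoid, stem and progenitor, dendritic and fibroblast or endothelial markers, ERK feedback, STAT5, FOXO, NF-kB and p53 targets, cytokines, cell cycle, apoptosis, glycolysis, cholesterol synthesis, ATF4 and amino acid stress, interferon response, ribosome biogenesis and PI3K components. Lists overlap: among measured genes, Gfi1 is in the progenitor and the granulocyte list, Osm in the STAT5 and cytokine lists, Tnf in the NF-kB and cytokine lists, Bcl6 in the STAT5 and FOXO lists, Bcl2l1 and Mcl1 in the STAT5 and apoptosis lists, and Cdkn1a in the STAT5 and p53 lists. Sesn1 and Gadd45a are in the FOXO and p53 lists, Bcl2l11 in the FOXO and apoptosis lists, Pmaip1 and Trp53inp1 in the apoptosis and p53 lists, Bbc3 in these and the FOXO list, and Sesn2 in the amino acid stress and p53 lists. A list's median difference was ranked among 10000 random lists of the same size. This describes these arrays and tests nothing. A list was called shifted where its percentile was under 2.5 or over 97.5 on the same side in both comparisons that share no array, and lists with under 5 measured genes were not ranked. The count adjusted over the list alone applies the Benjamini-Hochberg step to the list's own p-values, with no correction over the 22 lists.

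Named genes were Kit, the 12 highest and 12 lowest by the smaller of both genotype differences, the 8 highest and 8 lowest by the smaller of both SCF responses, the 6 highest and 6 lowest by the difference between the SCF responses, and up to 4 members of each list with the largest mean genotype or SCF difference. RIKEN clones and predicted genes were skipped. Other genes are said to be chosen after their values were seen or complete a count.

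Alternatives were cyclic loess and quantile normalization, filters at the 25th percentile and the median of all values, the probe set with the highest mean, leaving out probe sets ending in _x_at or _s_at, a size of 1.5-fold or 3-fold, an intensity trend or robust prior in eBayes, and a fit without the other factor. Centring each array on its median, and requiring every probe set of a gene to pass the size, were added after seeing the data. Loess, the filters, the intensity trend and the highest-mean probe set went by the relative level of these values and not by signal. They therefore cannot address effects of brightness. The median of all genes was -0.08 without SCF and -0.14 with SCF for the genotype difference, and became 0.03 and 0.04 after loess, -0.01 and 0.00 after quantile normalization and 0.01 and 0.01 after centring. Percentiles of lists are relative to other genes and so to this shift. Leaving out a replicate and other splits of the samples could not be run with 1 array per group.

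The fit was tested on simulated data with the means of the 6404 genes, the fitted variance prior and 50 changed genes at each size. For the genotype effect in the additive fit it recovered 4% of 50 genes changed by 0.5 on the log2 scale, 82% of 50 changed by 1, and 100% of those changed by 2 and by 4. It also called 8 unchanged genes, 5.3% of all calls. The simulated data held no SCF effect and no difference between the SCF responses. These rates hold for that model and do not give the share of false calls on the real arrays.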

Results

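Expression was measured in EML cells, a mouse lymphohematopoietic progenitor line that normally depends on stem cell factor (SCF), the ligand of the receptor tyrosine kinase KIT. The cells carried either the KIT mutant Del417-419insY, which alters the extracellular domain, or D816V, which alters the phosphotransferase domain of the kinase; both mutations occur in mastocytosis, a disease of mast cell accumulation. Per the labels' protocols the mutants were brought in by retrovirus, the transduced cells were selected for growth without added factor, and cells expressing KIT were sorted. Each line was profiled without SCF and with SCF at 250 ng/mL for 48 h. The culture time of the arrays without SCF is not given in the sources used here, so a difference with SCF may include one in culture time. This gave 4 groups of 1 array each, so no value below has a replicate, and the number of arrays limits the precision. The values were log2 levels relative to a zero that differs between probe sets, so differences between arrays can be read and absolute levels cannot. Array medians were -0.02 and -0.05 for Del417-419insY without and with SCF, and -0.10 and -0.20 for D816V. The D816V array with SCF had both the lowest median and the widest spread (SD 0.79 across probe sets, against 0.59, 0.72 and 0.59 on the others).

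The comparison of the mutants addresses how an extracellular and a kinase domain mutation of KIT differ in the expression they accompany. Kit itself was lower in D816V cells, by -1.07 on the log2 scale without SCF and -1.77 with SCF, and its 2 probe sets gave mean differences of -1.67 and -1.18. Which species of KIT the constructs carried, and whether these probe sets read it, is not given in the sources used here, so this value does not check the transgenes.

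The genes that separated the lines most encode proteins of unlike function. Gzma, which encodes the cytotoxic granule protease granzyme A, was 258-fold higher in D816V cells on average over both conditions (log2 difference 8.01, SE 0.22, limma adjusted p = 7.5e-05). Ifitm3, an interferon-induced membrane protein, was 166-fold higher, the aldo-keto reductase genes Akr1c12 and Akr1c13 were 169-fold and 118-fold higher, and the T cell receptor gamma segment Trgv4 was 94.8-fold higher. Akr1c12 and Akr1c13 are close paralogs, and so are the Trgv segments, and whether their probe sets read each other's transcripts was not tested. Fcer1a, the alpha chain of the high-affinity IgE receptor, was 66.7-fold higher, and Tph1, the rate-limiting enzyme of peripheral serotonin synthesis, was 41.2-fold higher. Metrnl, Arnt2, Gbp2, Crybg1 and Tspan8 followed at 41.1, 40.2, 35.8, 35.6 and 33.0-fold. In the other direction Tnni1, slow skeletal troponin I, was 85.0-fold lower in D816V cells (log2 difference -6.41, SE 0.12, limma adjusted p = 5.8e-05). Fap, the fibroblast activation protein, was 69.5-fold lower, the chemokine Ppbp of platelet granules 30.5-fold lower, and the adhesion receptor Cd44 24.2-fold lower. Ivl, Fat1, Ak8, Ms4a6b, Sstr2, Ddc, Trbv1 and Car1 were lower by 19.1, 13.4, 11.9, 11.9, 8.81, 8.81, 8.75 and 7.71-fold. These 24 genes all passed the test. They had been chosen by both differences on the same arrays, so passing is no separate support.

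**Figure D1:**
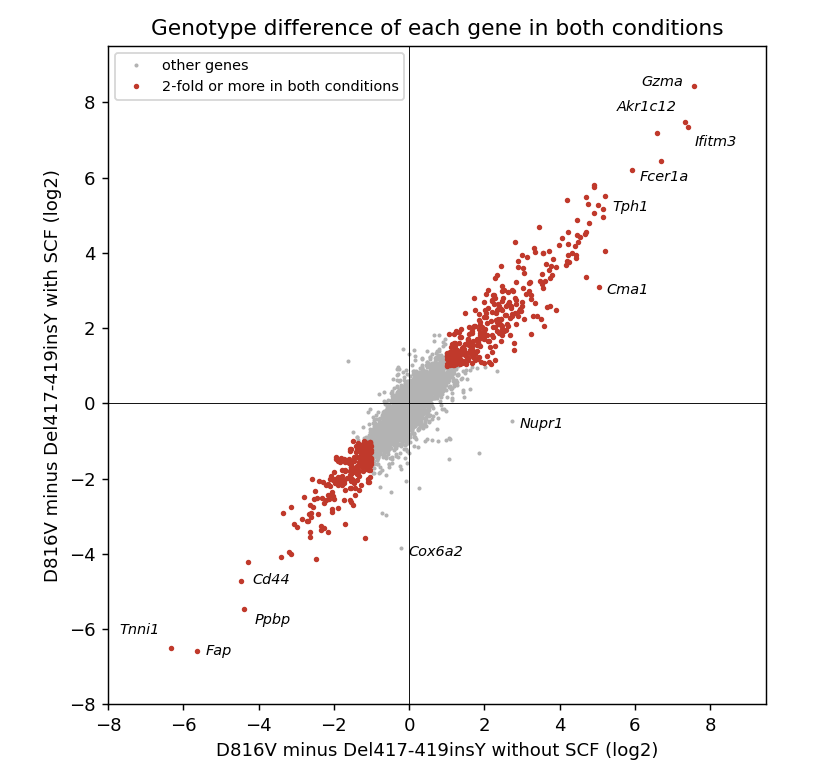
Difference between D816V and Del417-419insY cells for each of 6404 genes, in log2 units, without SCF on the horizontal axis and with SCF on the vertical axis; each point is a gene and red points differ by 2-fold or more in the same direction in both conditions. The 572 red points lie along the diagonal, from Gzma (7.58 and 8.44) to Tnni1 (-6.32 and -6.49), while Nupr1 (2.74 and -0.46) and Cox6a2 (-0.21 and -3.85) lie away from it.

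Over all 6404 genes the limma fit called 1147 higher and 1579 lower in D816V cells, 42.6% of them, a share to set beside each list count below. Genes of the interferon response stood far higher in D816V cells. Of the 15 measured members of this list 13 were higher, 1 was lower and 1 did not pass the test, and the counts adjusted over the list alone were the same, 13 and 1. The list's median difference was 2.58 without SCF and 3.36 with SCF, both at the 100th percentile of 10000 random lists of the same size. The medians were 2.19 and 1.88 after cyclic loess and 2.23 and 2.90 after quantile normalization, so the order of the list medians was not stable. Gene by gene, the genotype difference with SCF minus that without had a median of -0.17, with 9 of 15 genes below 0. After cyclic loess this median was -0.19, with 12 below 0. The typical member therefore did not differ more with SCF. Gbp2 and Iigp1, interferon-inducible GTPases, differed by 5.16 and 4.63 on the log2 scale, Ifit1 by 4.30 and the 2'-5' oligoadenylate synthetase-like gene Oasl2 by 4.23. The exception was Ifih1, a cytosolic sensor of double-stranded RNA, which was lower in D816V cells, by -2.80.

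Mast cell genes were higher in D816V cells as well. Of 19 measured members 16 were higher, none was lower and 3 did not pass (17 higher adjusted over the list alone), with medians of 1.15 without SCF and 0.86 with SCF, at the 100th percentile in both. Besides Fcer1a and Tph1, the list held Rab27b, a regulator of granule secretion, at 4.16, and Cma1, a mast cell chymase, at 4.07. The difference of Cma1 was 5.04 without SCF and 3.10 with SCF.

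Targets of STAT5, a transcription factor downstream of KIT and of cytokine receptors, were 10 higher and 1 lower among 14 measured genes, with the same counts adjusted over the list alone. Their medians were 1.60 and 1.53, both at the 100th percentile. Cish and Socs2, feedback inhibitors of cytokine signalling, were 17.1-fold and 15.2-fold higher, the kinase gene Pim1 7.20-fold and Socs1 4.81-fold higher. Bcl6 was lower (-1.12), and the list does not mark which targets STAT5 induces or represses. Secreted cytokines and growth factors gave 4 higher and none lower among 5 measured genes, also when adjusted over the list alone. Their medians of 1.20 and 0.61 lay at the 99.9th and 98.4th percentiles. Osm, also a STAT5 target, was at 2.00, Ccl9 at 1.91, Tnf at 0.83 and Tgfb1 at 0.61.

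Over all genes the fit called more lower than higher ones in D816V cells, a balance that turned to 1263 lower and 1628 higher after cyclic loess. Genes of stem and progenitor cells likewise included more lower than higher ones. Among 11 measured members 7 were lower and 1 was higher (8 and 1 adjusted over the list alone), with medians of -0.48 and -0.89 at the 1.04th and 0.02nd percentiles. The counts were 5 and 1 after cyclic loess, 4 and 1 without the SCF term, and 4 and 1 of 8 with the 25th percentile filter. Gfi1, Sox4 and Kit differed by -1.82, -1.71 and -1.42, while Slamf1 was higher, by 1.62. The cells were sorted for KIT, and whether the Kit probe sets read the constructs is not known, so Kit cannot serve as a progenitor marker here. Gfi1 did not pass with an intensity trend in the prior or with robust eBayes. This list was no longer shifted after cyclic loess scaling or with the 25th percentile filter, where its medians were -0.31 and -0.55, and -0.34 and -0.64.

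The erythroid, megakaryocyte, granulocyte and monocyte, and lymphoid lists had members on both sides and did not meet the criterion for a shift, and the dendritic and fibroblast lists had too few measured genes to be ranked. Erythroid genes were 2 higher and 5 lower of 13 (2 and 5 adjusted over the list alone), with the carbonic anhydrase gene Car1 at -2.95, Ermap at -1.71, the erythroid transcription factor Klf1 at -1.14 and Icam4 at 0.92. Megakaryocyte genes were 4 higher and 5 lower of 11 (4 and 6 adjusted over the list alone), with Ppbp at -4.93 and Nrgn at -1.56 against Itgb3, a fibrinogen receptor chain, at 2.26 and F2rl2 at 2.13. Granulocyte and monocyte genes were 3 higher and 5 lower of 16 (3 and 6 adjusted over the list alone), and 5 and 5 after cyclic loess. With the 25th percentile filter they were 3 and 2 of 8. Their medians of -0.10 without and -0.78 with SCF (39.0th and 0.01th percentiles) became 0.255 and -0.17 with that filter. Myeloperoxidase, Mpo, stood at -1.64 and the chemokine receptor Ccr2 at 2.88, although the 4 probe sets of Ccr2 ranged from 1.10 to 4.45. Lymphoid genes were 2 higher and 3 lower of 7 (3 and 3 adjusted over the list alone), with Ltb at 1.77 and Satb1 at -1.32. All 3 measured genes of dendritic cells and antigen presentation, Ccr7, Cd74 and Itgax, were higher, by 2.47, 1.85 and 0.93 (3 and 0 adjusted over the list alone). Neither of the 2 measured fibroblast and endothelial genes passed, over all genes or adjusted over the list alone: Pdgfrb was at -0.12, or 0.36 after cyclic loess, where it passed, and Pecam1 at -0.04.

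**Figure D2:**
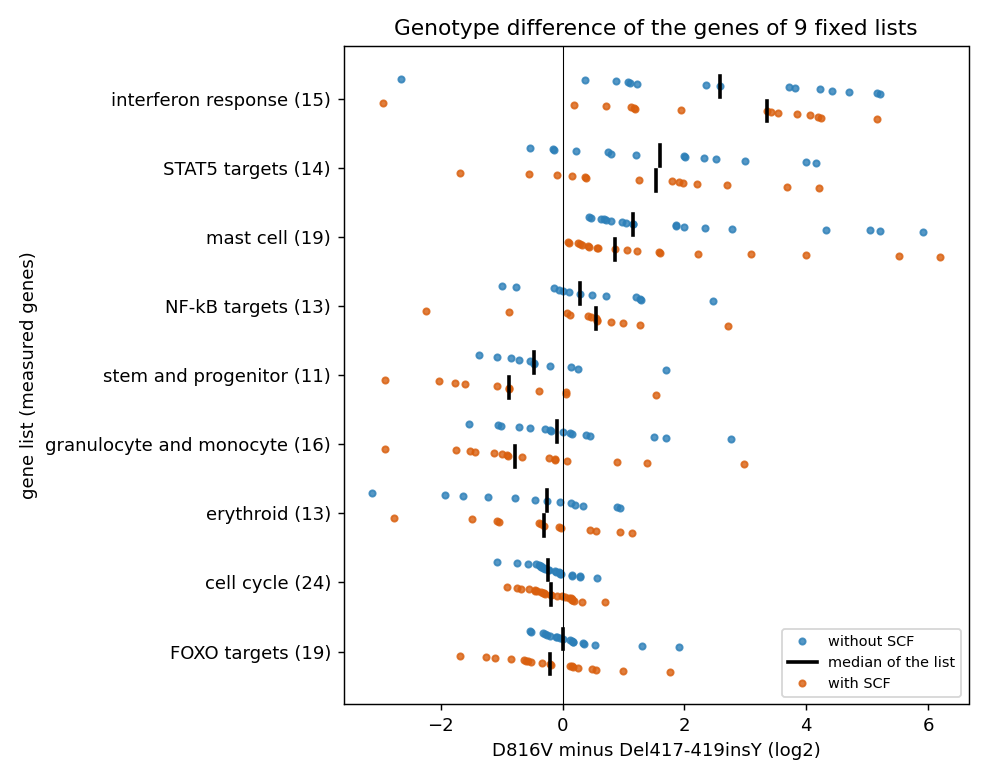
Log2 difference between D816V and Del417-419insY cells of the measured genes of 9 lists, without SCF (blue) and with SCF (orange); each point is a gene, black bars are list medians, and the number of measured genes stands behind each list name. Interferon response genes have medians of 2.58 and 3.36, with Ifih1 as the point far to the left, and stem and progenitor genes have medians of -0.48 and -0.89.

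A list count near or under the share of all genes called, 42.6%, does not set a list apart. The remaining lists, of signalling, growth and metabolism, did not meet the criterion for a shift between the mutants. NF-kB targets came nearest, with 7 higher and 2 lower of 13 (7 and 2 adjusted over the list alone) and medians of 0.28 and 0.55 at the 97.47th and 99.9th percentiles, and they were shifted with the 25th percentile filter, while the first median was 0.13 after cyclic loess. The chemokine gene Ccl5 stood at 2.59 and Ptgs2, inducible cyclooxygenase, at -1.50, which did not pass without the SCF term. ERK feedback and immediate early genes were 3 higher and 2 lower of 11 (3 and 2 adjusted over the list alone), with Etv5 at 1.52 and Junb at 1.35 against Ccnd1 at -1.32 and Fos at -1.24. Their median was 0.56 without SCF, at the 99.8th percentile, and -0.05 with SCF, at the 63.1st. After cyclic loess the medians were 0.40 and 0.09, at the 98.06th and 59.4th percentiles. FOXO targets were 2 higher and 2 lower of 19, also adjusted over the list alone, with Ddit4 at 1.84. PI3K and AKT pathway components were 3 higher and 4 lower of 12, also adjusted over the list alone, with the lipid kinase subunit Pik3cd at 1.46. Targets of p53 were 2 higher and 2 lower of 13 (1 and 2 adjusted over the list alone), with Perp at -1.23. Cell cycle genes were 1 higher and 7 lower of 24 (1 and 4 adjusted over the list alone), with Mcm6 at -0.71 and Kif11 at -0.66. This balance came with the scaling, since 3 were higher and 3 lower after both cyclic loess and quantile normalization, and 3 and 4 after centring. Of 12 apoptosis regulators 3 were higher and 1 was lower (3 and 0 adjusted over the list alone), and the highest were the survival genes Bcl2l1 (1.23) and Bcl2 (1.18). Ribosome biogenesis genes were 3 lower and none higher of 17, and none passed when adjusted over the list alone. Glycolysis genes were 3 higher and 3 lower of 14, also adjusted over the list alone, with the glucose transporter gene Slc2a3 at 2.22 and Pfkfb3 at -0.76. In cholesterol synthesis 1 of 16 genes was higher, and among amino acid stress genes 1 was higher and 1 lower of 17; adjusted over the list alone these became 0 of 16, and 1 higher and 0 lower. The differences of both lists depended on the condition. Cholesterol synthesis genes had medians of -0.24 without and 0.81 with SCF, at the 12th and 100th percentiles, and those of amino acid stress genes are given with the SCF responses. After cyclic loess FOXO targets were 6 higher and 4 lower, p53 targets 4 and 3, apoptosis regulators 5 and 0, ribosome biogenesis genes 1 and 2 and cholesterol synthesis genes 3 and 0. Without the SCF term NF-kB targets were 4 higher and 1 lower, p53 targets 0 and 2 and PI3K components 1 and 3. Glycolysis genes were then 1 and 2, cell cycle genes 1 and 3, and ribosome biogenesis genes 0 and 0.

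Counted by size alone, 403 of 6404 genes were 2-fold or more higher and 268 lower in D816V cells without SCF, and 406 were higher and 475 lower with SCF. In both conditions 330 genes were higher and 242 lower, where independent lists of these sizes would share 25.5 and 19.9. These conditions share no array, and their differences had a Pearson correlation of 0.92 and a Spearman correlation of 0.85 across genes, which are not independent replicates. The limma fit with genotype and SCF as additive terms called 1147 genes higher and 1579 lower at an adjusted p under 0.05. All of the 330 and 242 were among them. Those had been chosen by both differences on the same arrays, so their passing is no separate support. The fit takes the difference between the SCF responses for error and has no replicate array. Each mutant was 1 cell population, so these p-values cover neither the spread between repeat arrays nor that between populations. Scaling decided the balance of the fit: cyclic loess gave 1628 higher and 1263 lower, quantile normalization 1526 and 1387, and median centring, chosen after the data were seen, 1720 and 1302. For the size count with SCF, loess gave 453 higher and 325 lower and centring 494 and 347. Without the SCF term the fit called 1603 genes.

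The comparison of arrays with and without SCF addresses what added ligand does in each mutant line. In Del417-419insY cells 21 genes were 2-fold or more higher and 35 lower with SCF, and in D816V cells 21 and 84. Shared by both lines were 2 higher and 15 lower genes, where independent lists would share 0.069 and 0.46. With the highest-mean probe set the counts were 23 and 96 in Del417-419insY cells, 26 and 145 in D816V cells, and 3 and 52 in both. Ankrd37, a hypoxia-responsive gene, differed by 1.40 in Del417-419insY and 1.82 in D816V cells, and Rflna by 1.07 and 1.22. Gramd3, Scpep1, Upp1, Car2, Dglucy and Smtn followed with means over both lines of 0.97, 0.95, 0.89, 0.96, 0.79 and 0.70. On the lower side were the mast cell protease genes Mcpt4, with -2.14 and -1.77, and Tpsb2, with -1.95 and -1.33. The other measured protease genes of the mast cell list were not all lower in both lines. Cma1 stood at 0.755 and -1.192, Mcpt2 at 0.402 and -1.081 and Mcpt8 at -0.065 and -1.005. Fgfr1op2, Scai, Nck2, Neil3, Inpp4b and Lpxn had means of -1.61, -1.46, -1.41, -1.33, -1.32 and -1.32. The genes named from Ankrd37 to Smtn, Mcpt4, Tpsb2 and those from Fgfr1op2 to Lpxn each had 1 probe set. No other probe set could therefore check their SCF differences. None of these differences passed the limma test, which called 0 genes for SCF; 1186 of 6404 genes had an unadjusted p under 0.05, and the smallest adjusted p was 0.089. The fit called 2 genes after quantile normalization, 10 with an intensity trend in the prior, 42 after cyclic loess, and 256 both after centring and with the highest-mean probe set. The size counts in D816V cells became 34 higher and 50 lower after loess, 23 and 35 after quantile normalization and 32 and 62 after centring. Quantile normalization gave 41 and 45 in Del417-419insY cells and 3 and 9 in both lines.

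Glycolysis was the only list shifted by SCF in both lines, with medians of 0.27 in Del417-419insY and 0.29 in D816V cells at the 99.9th and 100th percentiles. The list is not confined to glycolytic enzymes. Bnip3 and the glucose transporter gene Slc2a1 had mean differences of 0.92 and 0.64, and the enzyme genes Pfkl and Aldoa of 0.61 and 0.49. Adjusted over the list alone, 5 of 14 genes were higher and none lower. Erythroid genes had medians of 0.23 and 0.11 (98.8th and 93.4th percentiles; 3 higher and 0 lower adjusted over the list alone) and were also shifted under cyclic loess and with the highest-mean probe set. Ribosome biogenesis genes had medians of -0.29 and -0.19, at the 0th and 5.3rd percentiles (0 higher and 5 lower adjusted over the list alone), with Nop58 at -0.89 and Noc2l at -0.78. Cell cycle genes had medians of -0.13 and -0.17. In D816V cells the medians of these lists were 0.25 for erythroid, -0.08 for ribosome biogenesis and -0.04 for cell cycle genes after cyclic loess. Adjusted over the list alone, 4 mast cell genes were lower, 2 STAT5 targets were higher and 2 lower, 2 granulocyte and monocyte genes were higher and 2 lower, 2 FOXO targets were higher and 1 lower, 1 dendritic cell gene was higher and 1 lower, 1 stem and progenitor gene was lower and 1 p53 target was higher. In the remaining lists no gene passed.

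The lines differed in their SCF response for genes of amino acid stress, the programme controlled by the transcription factor ATF4. With SCF the 17 measured genes had a median of 0.20 in Del417-419insY cells, at the 99.5th percentile, and of -0.84 in D816V cells, at the 0th percentile. With the highest-mean probe set the former was 0.10, at the 88.0th percentile, and 4 genes lay below 0 in place of 1. All 17 lay lower in the response of D816V than in that of Del417-419insY cells, with a median difference of -0.89. Trib3, a pseudokinase induced by amino acid shortage, differed by 1.43 with SCF in Del417-419insY and -1.75 in D816V cells, the glutathione-degrading enzyme gene Chac1 by 0.34 and -2.19, and Atf5 by 0.99 and -1.50. Psat1 and Cars, of serine synthesis and tRNA charging, stood at 0.01 and -0.84 and at 0.02 and -0.90. Nupr1, a stress-induced chromatin protein outside the list, showed 1.48 and -1.72. Without SCF this list was higher in D816V than in Del417-419insY cells (median 0.29, 99.4th percentile), and with SCF it was lower (median -0.90, 0th percentile); after cyclic loess these medians were 0.46 and -0.59.

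Genes of cholesterol synthesis showed the opposite, with a median difference between the responses of 0.99. Their median SCF response was -0.03 in Del417-419insY and 0.94 in D816V cells, at the 24.1st and 100th percentiles, and all 16 measured members were above 0 in D816V cells. Pmvk and Mvd, of the mevalonate pathway, stood at 0.16 and 1.46 and at 0.47 and 1.37, Fdft1, squalene synthase, at 0.15 and 1.23, and Idi1 at -0.84 and 0.76. Other genes with a higher response in D816V cells were the embryonic globin gene Hbb-bh1 (-1.66 and 1.11), Itih5 (-0.09 and 1.39), Fam220a (-0.44 and 0.85) and Ccdc25 (-0.62 and 0.62). Cox6a2, a subunit of cytochrome c oxidase of striated muscle, had the lowest, with 1.36 and -2.28, and the ATP-gated channel gene P2rx3 stood at 0.33 and -2.07.

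**Figure D3:**
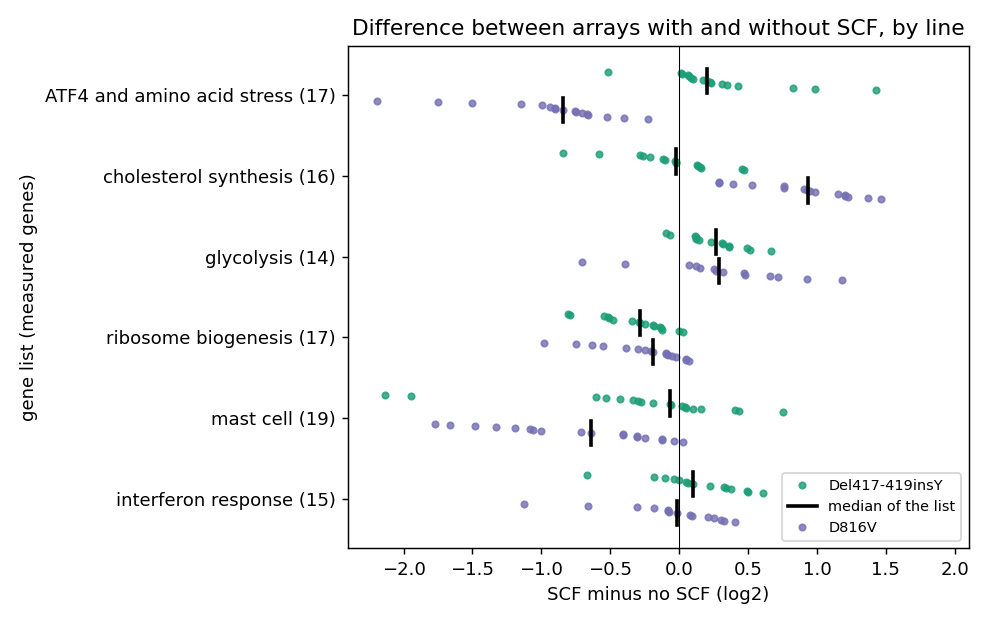
Log2 difference between arrays with and without SCF for the measured genes of 6 lists, in Del417-419insY cells (green) and D816V cells (purple); each point is a gene and black bars are list medians. All 17 amino acid stress genes lie below 0 in D816V cells (median -0.84) and all 16 cholesterol synthesis genes above 0 (median 0.94), while the medians in Del417-419insY cells are 0.20 and -0.03.

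Several other lists had a lower median with SCF in D816V than in Del417-419insY cells, a difference that was not tested, and none met the criterion for a shift in both lines. Mast cell genes had a median of -0.64 there (0th percentile) against -0.07 in Del417-419insY cells (7.59th percentile). Hpgds, prostaglandin D synthase, stood at -1.48 against -0.30 and Ms4a2, the beta chain of the IgE receptor, at -1.67 against -0.60. ERK feedback genes had a median of -0.50 against 0.04, stem and progenitor genes of -0.55 against 0.11, granulocyte and monocyte genes of -0.34 against 0.17, and p53 targets of -0.31 against 0.05. These D816V medians depended on the scaling. After cyclic loess they were -0.36 for mast cell, -0.36 for ERK feedback, -0.34 for stem and progenitor, -0.13 for granulocyte and monocyte genes and -0.08 for p53 targets, the last at the 11.3rd percentile. After quantile normalization they were -0.47, -0.31, -0.15, -0.03 and -0.14 in the same order. With the highest-mean probe set the stem and progenitor median was -0.20, at the 10.4th percentile. NF-kB targets went the other way in D816V cells, with a median of 0.37 (100th percentile) against 0.14 in Del417-419insY cells (89.3rd), or 0.39 against 0.21 after cyclic loess and 0.18 against 0.14 with the highest-mean probe set. Birc3 stood at 0.68 and 0.41, and Ptgs2 at -1.78 and -0.31. FOXO and STAT5 targets stood higher in Del417-419insY cells, with medians of 0.25 and 0.19 (99.96th and 98.2nd percentiles), against -0.07 and -0.07 in D816V cells, which turned to 0.01 and 0.08 after cyclic loess, 0.02 and 0.04 after quantile normalization and 0.02 and 0.03 after centring. The interferon list had SCF medians of 0.10 in Del417-419insY and -0.02 in D816V cells (79.8th and 54.5th percentiles), and after cyclic loess 0.22 and 0.03 (97.7th and 33.8th percentiles). By size, 22 genes had an SCF response 2-fold or more higher in D816V cells and 90 a lower one. These numbers became 33 and 56 after cyclic loess, 28 and 57 after quantile normalization and 28 and 66 after median centring. No degree of freedom is left to test this difference. Across genes the SCF responses of the lines had a Pearson correlation of 0.45 and a Spearman correlation of 0.46.

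**Figure D4:**
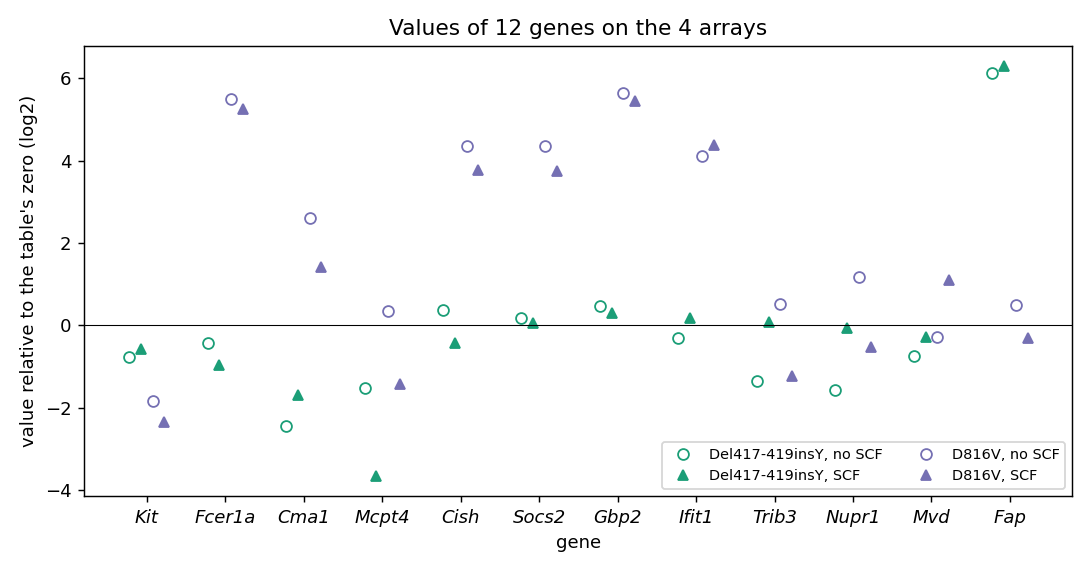
Log2 values of 12 genes on the 4 arrays, relative to the zero of each probe set; circles are arrays without SCF, triangles arrays with SCF, green is Del417-419insY and purple is D816V, with 1 array per group. Fcer1a, Cish, Socs2, Gbp2 and Ifit1 lie higher on both D816V arrays, Fap lies lower on both, and Trib3 and Nupr1 change places between the conditions.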

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

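The requirement on random lists after scaling was added after the values for amino acid stress genes were seen; the test after cyclic loess itself was chosen before. Several SCF responses had opposite directions in the lines. Hbb-bh1 stood at -1.66 in Del417-419insY and 1.11 in D816V cells, a difference of 2.77 on the log2 scale. Cox6a2 stood at 1.36 and -2.28, a difference of -3.64, Nupr1 at 1.48 and -1.72 (-3.20) and Trib3 at 1.43 and -1.75 (-3.18). For Chac1 the genotype difference turned from 1.05 without SCF to -1.49 with SCF, by -2.54. With 1 array per group these differences were not tested, and no group was large enough to look for an array apart from its replicates.

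The amino acid stress list, to which Trib3 and Chac1 belong, had a median SCF response of 0.20 in Del417-419insY and -0.84 in D816V cells, and its median genotype difference was 0.29 without and -0.90 with SCF (0.46 and -0.59 after cyclic loess). The median difference between the responses, the same quantity from either side, was -0.89, and it too was not tested. A scaling difference between the arrays would have to shrink this value, which became -0.79 after cyclic loess and -0.72 after quantile normalization, with all 17 genes still below 0 in both and the list at the 0th percentile of random lists after loess. The bound set beforehand for loess was -0.75, passed by less than the spread of the median (0.050), and the quantile value lies on its other side. So the scalings argue against scale as the whole source and leave a part open. The state of the single cultures at harvest, such as density or spent medium, may equally produce this pattern: with 1 array per group it cannot be told apart from an effect of SCF that depends on the mutant, which remains open as well.

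Probe sets outside the gene counts also separated the lines. Among those without a gene symbol 112 differed by 2-fold or more in both conditions, 31 higher and 81 lower in D816V cells. Among those with several symbols 30 did, 21 higher and 9 lower. The latter included probe sets for Trgv4 and Trgv2 with a mean difference of 7.89, for Akr1c12 and Akr1c13 with 7.49, for the interferon-inducible GTPases Tgtp1 and Tgtp2 with 6.93, for Gvin1 and Gm4070 with 6.06 and for Lilrb4a and Lilr4b with 4.92.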

How the results depend on the processing

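Median centring and the requirement that every probe set pass were chosen after seeing the data. The genotype counts over all genes, unlike those of single lists, stayed within 1.5 times the reported ones under every scaling, filter and probe set choice tried. Of the 572 genes 2-fold apart in both conditions, 468 were shared with the 530 after loess, 525 with the 576 after quantile normalization and 544 with the 584 from the highest-mean probe set. Results on SCF moved more, and the cause was not tested unless given. Quantile normalization gave 86 genes for SCF in Del417-419insY, 58 in D816V and 2 in the fit. The fit called 42 genes after loess, 10 with an intensity trend and 256 after centring. The highest-mean probe set gave 119, 171 and 55 genes in Del417-419insY, D816V and both lines, including all 17 of the reported ones, and 256 in the fit. It and loess each shifted 2 lists by SCF, glycolysis and erythroid genes. Leaving the SCF term out of the genotype fit gave 1603 genes. The size itself changed each count by construction. At 1.5-fold 1592 and 2151 genes differed between the mutants without and with SCF and 1316 in both, 320 and 576 with SCF in Del417-419insY and D816V and 120 in both, and 516 between the responses. At 3-fold these were 325, 382, 272, 7, 16, 1 and 19. Pdgfrb turned to 0.36 under loess. Among the other comparisons of a named gene's genotype effect with an alternative, 973 kept direction and side of the threshold, 17 fell out and 17 came in. For SCF effects 842 kept both and 93 came in. Because 0 genes passed for SCF as reported, those 842 only stayed unpassed and none could fall out, so they do not show stable SCF effects. No paired analysis was possible because each group held 1 array, so no replicate could be left out either. Signal over background was not examined, since the values are relative.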

Other observations

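The gene groups in the next paragraph were chosen after the values were seen, as were the tests against ligand responses further on; the tests of scaling and of probe sets were chosen before. Genes that present peptides on MHC class I were higher in D816V cells. All 15 measured members of 16 lay above 0 in both conditions, with medians of 0.92 without and 0.67 with SCF, and 12 passed the limma test. H2-D1 differed by 3.01, H2-K1 by 2.30, Nlrc5, their transactivator, by 2.14, the immunoproteasome gene Psmb9 by 1.72 and the peptide transporter gene Tap1 by 1.32. All 7 measured interferon-inducible GTPase genes of 12 were higher, with medians of 3.04 and 3.06, or 2.13 and 1.88 after cyclic loess, among them Gbp7 at 4.08 and Gbp6 at 3.05. Gbp2, Iigp1 and Igtp are also in the interferon list. Cytosolic tRNA synthetase genes outside the amino acid stress list had median SCF responses of 0.08 in Del417-419insY and -0.45 in D816V cells, and 13 of 15 had the lower response in D816V. The D816V median was -0.18 after cyclic loess and -0.23 after quantile normalization, and the median difference between the responses went from -0.47 to -0.25 and -0.28. For Sars, Yars, Nars and Lars the difference was -1.03, -0.92, -0.94 and -0.90. For 5 mitochondrial synthetase genes the medians were 0.02 and -0.08, the latter 0.01 after quantile normalization and after centring. Gzmc, a granzyme gene, and Il4ra were higher in D816V cells, by 3.69 and 2.35, and Il5ra lower, by -2.04.

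Interferon response genes were higher in D816V cells without and with SCF. A scaling difference of the kind that cyclic loess removes cannot carry this. The list's median of 2.89 over both conditions was 2.08 after loess, where a value above 1 had been set beforehand to count against scaling. On relative values loess cannot address effects of absolute brightness. If the kinase mutant acted as added ligand does, the list would respond to SCF in Del417-419insY cells, and its median response there was 3.47% of the genotype difference (0.10 on the log2 scale, or 0.22 after cyclic loess). This excludes nothing, because ERK feedback genes, chosen as the positive control, stood at the 54.2nd percentile in the same arrays. A difference between the transduced populations other than the KIT variant, such as a response to the vector or a clone that outgrew the rest, may equally be the source, since each group has 1 array and each mutant 1 population.

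For the STAT5 targets and mast cell genes that were higher in D816V cells, the same ligand test gave 12.04% and -5.09% of the genotype difference. It could not exclude that the kinase mutant acts as strong KIT signalling would, for want of a working positive control. Both populations had also been selected to grow without factor. For STAT5 targets the missing control was not the only reason. Their own median SCF response in cells of the extracellular mutant was 0.19, at the 98.2nd percentile of random lists.

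SCF responses had the same direction in both lines for more genes than independent lists would share. Probe sets that do not follow their gene are a candidate source. For 100 genes whose first probe set differed by 0.5 or more the same way in both lines, the other probe sets gave a median of 0.37 of its response, between the bounds set beforehand, and 85% had its sign. The ratio was 0.30 for 85 genes that stood lower and 0.59 for 15 that stood higher, against 0.89 for genotype differences of 618 genes. Choosing genes by the first probe set on the same arrays can by itself lower the ratio, more so where differences are small. The SCF and genotype ratios are therefore not alike, and the test cannot decide on this source. Handling of the arrays with and without SCF as separate sets could give such responses too, and 0 arrays carry a label of a handling batch, so it cannot be told apart from an SCF effect, which stays open. A difference in culture time stays open too, since a time is given for the arrays with SCF alone.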
